A study of Arabidopsis thaliana with 12 samples.

How the data were processed

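Messenger RNA of rosette leaves of Arabidopsis thaliana was sequenced in 12 libraries. The plants were 3 weeks old, had not bolted, and grew on soil with 16 h of light and 8 h of dark, per the labels. The accessions Col and C24 and their reciprocal F1 hybrids, named ColxC24 and C24xCol as in the labels, were sampled at zeitgeber times 0, 6 and 15 (ZT0, ZT6 and ZT15; hours). Each combination of genotype and time had 1 library, so there were no replicates.

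The deposited values are RPKM (reads per kilobase of gene model, scaled to the mapped reads of the library), per the file headers, with a value for each of 38710 gene models. Reads were 84 bp long and the genome build was TAIR9, per the labels. The aligner, the counting tool and the treatment of reads with several matches are not given in the sources used here. Whether reads of C24 that differ from the build were lost in mapping was not tested. Of values up to 1 read, 26.8 to 37.8% lay within 1% of 0.5 of a read in genes with 2 models, depending on the library, and 7.31 to 13.6% in genes with 1 model. Within 1% of 1/3 of a read lay 15.6 to 47.9% in genes with 3 models and 3.29 to 6.47% in genes with 1 model. A division of shared reads between models predicts such shares, although other fractions were left unexplained. The models of each gene were summed, which gave 32592 loci. Gene names came from the TAIR10.1 annotation, which named 31786 of them. No positions are given because the gene models and the names came from different releases.

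In genes with 1 model, 32.1 to 37.1% of values under 3.5 reads, depending on the library, lay within 1% of a whole number of reads. These steps gave an estimated depth of 16.8 M reads (Col at ZT0) to 26.8 M reads (Col at ZT15), where M stands for 1e6. In the shallowest library 1 read on 1 kb of transcript was worth 0.0596 RPKM. Pairwise Pearson r of log2(RPKM + 1) across genes lay between 0.8415 and 0.9928; genes are not independent replicates.

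RPKM values are not counts, so no count model was used. The 17207 loci with a mean of at least 1 RPKM were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). Parents, reciprocal hybrids and times were compared in an additive fit of genotype and time to the 12 libraries. Its spread is the genotype-by-time residual with 6 degrees of freedom, and all p-values rest on such a residual in place of replicates. Hybrids were compared with the mid-parent, the linear mean of both parents at each time, over 9 columns with 4 residual degrees of freedom. An F test with 2 residual degrees of freedom asked whether the departure from the mid-parent depended on time.

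At a single time no test was made. Genes were counted by a rule of size: both hybrids at least 1.5-fold above the higher parent, or below the lower parent, on RPKM + 1. The same rule was applied to the other two pairings of the 4 libraries. Of 18 gene lists with 365 genes, 364 genes were in the files and 294 were tested. The 17 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, for parents, mid-parent and reciprocal hybrids. At each time, the median of a list was set beside 10000 random lists of the same size matched on mean expression. Genes with at least 5 RPKM in each library of one parent and at most 0.1 in each of the other gave the hybrid level relative to the expressing parent.

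The tests, lists, rule for named genes and most alternatives were set before the data were examined. For each comparison the rule took the 8 called genes with the largest change in each direction that had the same sign at each time (in each genotype for times) and a mean of at least 3 RPKM. It added up to 4 called members of each list with the smallest adjusted p, and CCA1, LHY, TOC1, GI, FLC, FT and PR1 whatever their result. At each time it took the 4 genes above and the 4 below both parents with the widest gap. The text describes a part of these genes; a gene outside the rule is named as such.

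The fits were tested on simulated data. For changes of 1 and 2 on the log2 scale, 74 and 96% of 100 changed genes each were recovered between parents, 85 and 99% against the mid-parent, and 67 and 97% between reciprocal hybrids. For the dependence on time, 10% were recovered at a change of 2 and 77% at 4. In the simulated data the other genes did not differ between genotypes, errors were independent between genes, and no library was shifted as a whole. The real data do not meet these conditions, so these shares can overstate the recovery in them. Of 200 simulated lists without a change, 5.0% lay outside the central 95% of random lists. These lists were drawn at random from independent genes, so about this share was fixed in advance. In the real lists, the estimated correlation in the fit of the parents lay between -0.00233 (auxin, elongation and cell cycle) and 0.718 (cold response). The random lists do not carry it, so their central 95% can be too narrow for real lists.

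Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, empirical Bayes without a trend, a mid-parent on the log2 scale, each hybrid alone, a 2-fold gap, an estimated correlation, and leaving out times, genotypes or libraries. Taking the highest gene model, leaving out organelle and ribosomal RNA loci, and leaving out single hybrid libraries from the mid-parent comparison were chosen after seeing the data. The mid-parent on the log2 scale was a contrast in the additive fit of the 12 libraries, so the residual changed with it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.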

Results

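Transcript levels in rosette leaves were measured in Col, C24 and both reciprocal F1 hybrids at ZT0, ZT6 and ZT15, with 1 library for each of the 12 combinations. The estimated depth was 16.8 to 26.8 M reads per library. The title of the series names natural variation, the timing of stress responses and heterosis. The comparisons address how the parents differ, how hybrids stand to their parents, and how transcripts differ between the sampled times. Levels are RPKM of single libraries without replicate error, and changes are log2 differences with the standard error of the limma fit.

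The first comparison asked how C24 differed from Col. FLC, a repressor of flowering, was at 94.0, 53.8 and 99.3 RPKM in C24 at ZT0, ZT6 and ZT15, and at 0.139, 0 and 0.0895 RPKM in Col (log2 change 6.23, SE 0.15, adjusted p = 1.8e-08, higher at 3 of 3 times). PR1, a marker of salicylic acid responses, was at 1019, 125 and 1158 RPKM in C24 and at 7.92, 0.0501 and 0.885 RPKM in Col (log2 change 7.67, SE 0.50, adjusted p = 9.5e-06). FT, which promotes flowering, was lower in C24 (log2 change -2.53, SE 0.43, adjusted p = 0.0048), and the call was lost without ZT0 (adjusted p = 0.065). The widest decreases were those of ARGAH2, an arginase gene (log2 change -8.19, SE 0.83), and ECS1 (log2 change -8.01, SE 0.51). ARGAH2 was at most 0.1 RPKM in each C24 library, where a silent gene was not told apart from one absent or not mapped.

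Of 27 tested genes of salicylic acid and biotic defence, 9 were higher in C24 and 0 lower, and 20 were higher when adjusted over the list alone. They included NUDT6 (log2 change 3.86, SE 0.31), PR2 (3.12, SE 0.32) and PAD4 (1.75, SE 0.18). Camera called the list higher (adjusted p = 4.4e-15), a call lost with an estimated correlation (adjusted p = 0.43 with an estimated correlation). Of 24 glucosinolate genes, 5 were higher and 4 lower, and 7 and 4 adjusted over the list alone. ESP, the epithiospecifier protein gene, was higher by 6.18 (SE 0.29) and MAM3, a chain elongation gene, by 5.67 (SE 0.40), while ESM1 was at 446 RPKM in Col and 15.1 in C24 at ZT0 and was called lower. The camera call of this list (adjusted p = 6.9e-04) was also lost (adjusted p = 0.81 with an estimated correlation).

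Of 20 genes of the light-harvesting antenna, 5 were higher and 1 lower, and 8 and 2 adjusted over the list alone, among them LHCB4.3 (log2 change 1.42, SE 0.16) and LHCB6 (0.77, SE 0.14), whose call was lost without ZT0 (adjusted p = 0.093). Camera called this list higher (adjusted p = 7.6e-05; adjusted p = 0.43 with an estimated correlation). Flowering time had 3 of 16 genes higher and 5 lower, and 4 and 6 adjusted over the list alone; MAF4 was higher by 1.98 (SE 0.16), and FLM, named MAF1 in the annotation, changed by -3.46 (SE 0.14). Starch metabolism had 1 of 27 higher and 5 lower, and 1 and 11 adjusted over the list alone. Auxin, elongation and cell cycle had 1 of 14 higher and 3 lower, and 1 and 5 adjusted over the list alone.

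Cold response had 2 of 12 lower (4 adjusted over the list alone), jasmonate and wounding 2 of 22 lower (1 adjusted over the list alone), and abscisic acid and drought 2 of 23 lower (2 adjusted over the list alone). The morning-phased clock had 1 of 12 lower (1 adjusted over the list alone), oxidative stress 1 of 12 higher (1 adjusted over the list alone), and DNA methylation and small RNA 1 of 20 lower (0 adjusted over the list alone). The evening-phased clock, chlorophyll biosynthesis, ethylene, heat shock and senescence had 0 called on either scale with limma. Camera called none of the lists other than the 3 above, with adjusted p from 0.098 (chlorophyll biosynthesis and oxidative stress) to 0.83 (senescence). For flowering time, heat shock and DNA methylation the median and mean were negative while camera, which compares a list with other genes, pointed up; for senescence the median was negative and the mean positive. CCA1, LHY, TOC1 and GI of the circadian clock did not pass (adjusted p = 0.40, 0.19, 0.29 and 0.23).

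At ZT6 the Col library stood apart in cold-response genes. COR15A, a cold-regulated gene, was at 1768 RPKM in Col and 31.1 in C24 at ZT6, and at 3.85 and 2.07 RPKM at ZT0. The median of the cold-response list for C24 minus Col was -2.77 at ZT6, -0.10 at ZT0 and -0.64 at ZT15, and that of the jasmonate list was -1.54 at ZT6. COR15A (log2 change -3.19, SE 0.87, adjusted p = 0.040) and KIN2 (-1.83, SE 0.40, adjusted p = 0.017) were no longer called without the Col library of ZT6, at -1.83 (adjusted p = 0.065) and -1.46 (adjusted p = 0.068). Without ZT6 they were at -1.89 (adjusted p = 0.059) and -1.27 (adjusted p = 0.073), and without ZT15 at -3.22 (adjusted p = 0.24) and -1.66 (adjusted p = 0.22). Both calls were also lost without Col ZT15 (adjusted p = 0.072 and 0.062) or C24 ZT15 (adjusted p = 0.16 and 0.088). That of COR15A was lost with quantile normalization or no filter, and without C24 ZT6 (adjusted p = 0.095), ColxC24 ZT0 or C24xCol ZT0 (0.057 each), or ColxC24 ZT15 or C24xCol ZT15 (0.058 and 0.050).

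In all, 2337 of 17207 genes were called between the parents, 767 higher and 1570 lower in C24. With median-of-ratios scaling 1075 were higher and 1056 lower, and with quantile normalization 1157 and 975, so the balance of directions depended on the scaling. The count was 507 without ZT15, 766 without ZT0, and 1502, 1551, 1287 and 1082 without the single libraries Col ZT0, Col ZT6, Col ZT15 and C24 ZT15.

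**Figure D1:**
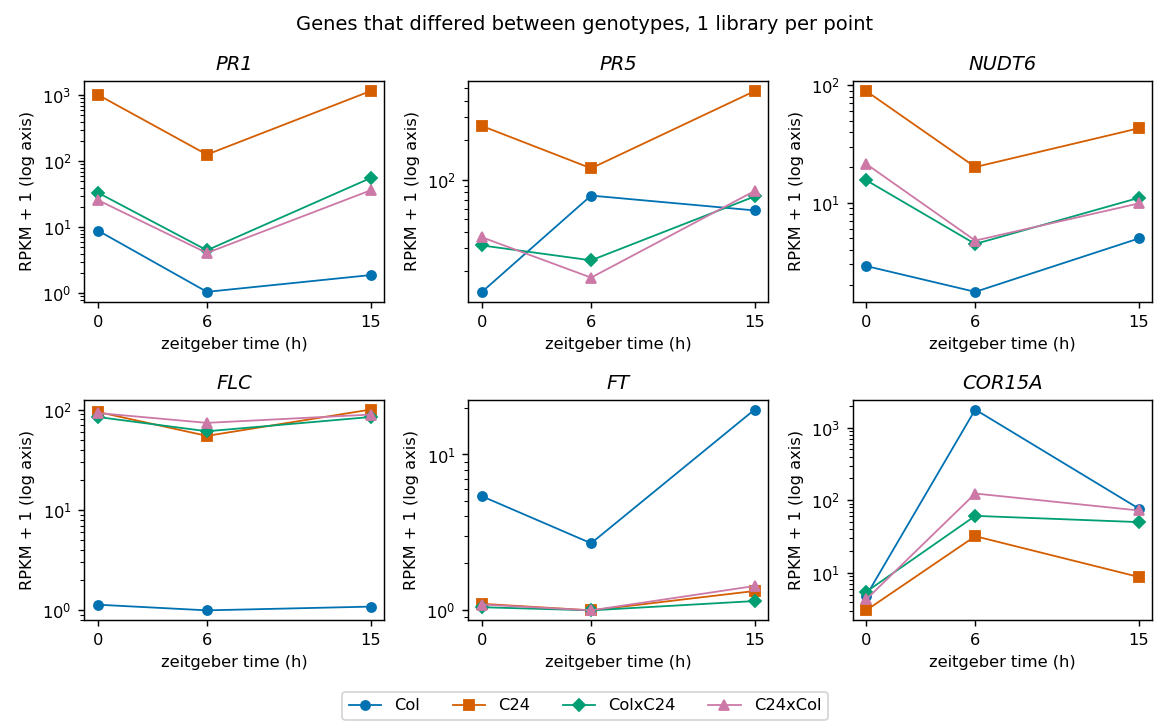
RPKM + 1 on a log axis against zeitgeber time in hours; each point is 1 library, coloured by genotype, and no group has replicates or error bars. PR1 was higher in C24 than in the other genotypes at each time, FLC was near 0 in Col, and COR15A reached 1768 RPKM in Col at ZT6.

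The second comparison asked whether hybrids departed from the mean of their parents. PR1 was at 32.5 RPKM in ColxC24 and 24.8 in C24xCol at ZT0, against 1019 in C24 and 7.92 in Col, and lay below the mid-parent (log2 change -3.91, SE 0.12, adjusted p = 6.0e-05, lower at 3 of 3 times). PR5, another pathogenesis-related gene (log2 change -2.02, SE 0.14, adjusted p = 0.011), and NUDT6 (-1.26, SE 0.11, adjusted p = 0.033) lay below it as well. UGT74F2, a glucosyltransferase gene, was at 21.6 RPKM in Col, 3.80 in C24, 3.27 in ColxC24 and 5.93 in C24xCol at ZT0 and was also below the mid-parent (log2 change -1.26, SE 0.13, adjusted p = 0.044). FLC did not pass (log2 change 0.98, SE 0.11, adjusted p = 0.074).

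Most of these calls were lost against a mid-parent on the log2 scale. That comparison used the fit of the 12 libraries with 6 residual degrees of freedom. The residual therefore changed along with the mid-parent, and their parts in the lost calls were not told apart. Against a mid-parent on the log2 scale, which lies lower for genes that differ widely between parents, PR1 was at -1.06 (adjusted p = 0.26), PR5 at -1.38 (adjusted p = 0.21) and NUDT6 at -0.22 (adjusted p = 0.79), while UGT74F2 was still called (-0.82, adjusted p = 0.011). FLC was above it (log2 change 3.11, adjusted p = 1.6e-06), and was also called against the linear mid-parent without the C24xCol library of ZT6 (log2 change 0.92, adjusted p = 0.044).

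Of these, PR1 alone was called against the linear mid-parent in every other alternative. PR5 was lost without a filter (adjusted p = 0.065), without ZT0 (0.40) or ZT15 (0.24), and without ColxC24 ZT0 (0.093), C24xCol ZT0, ColxC24 ZT6 (0.063 each) or ColxC24 ZT15 (0.065). NUDT6 was lost without a filter (adjusted p = 0.13), with ColxC24 alone (0.062) or C24xCol alone (0.079), without ZT0 (0.41), ZT6 (0.10) or ZT15 (0.57), and without ColxC24 ZT0 (0.096), C24xCol ZT0 (0.085), ColxC24 ZT6 (0.14), ColxC24 ZT15 (0.065) or C24xCol ZT15 (0.14). UGT74F2 was lost with median-of-ratios scaling (adjusted p = 0.12), quantile normalization (0.11), pseudocounts of 0.1 (0.098) and 0.5 (0.064), no filter (0.23), a mean of at least 5 RPKM (0.069), and ColxC24 alone (0.069) or C24xCol alone (0.23). It was also lost without ZT0 (adjusted p = 0.41), ZT6 (0.10), ZT15 (0.57), ColxC24 ZT0 (0.15), C24xCol ZT0 (0.11), ColxC24 ZT6 (0.14), ColxC24 ZT15 (0.18) or C24xCol ZT15 (0.14).

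In the defence list 3 of 27 genes were below the mid-parent and 6 adjusted over the list alone, with 0 above. Camera called this list lower (adjusted p = 9.3e-05; adjusted p = 0.96 with an estimated correlation). Of 20 antenna genes 0 were called over all genes with limma, while 14 were above the mid-parent adjusted over the list alone, with a list median of 0.30 (camera adjusted p = 4.1e-28; adjusted p = 0.070 with an estimated correlation). Glucosinolate genes had 0 called and 4 of 24 above adjusted over the list alone (camera adjusted p = 2.3e-12; adjusted p = 0.20 with an estimated correlation). Starch metabolism (camera adjusted p = 5.3e-08; adjusted p = 0.45 with an estimated correlation) and chlorophyll biosynthesis (camera adjusted p = 9.7e-06; adjusted p = 0.50 with an estimated correlation) were called higher with 0 genes called on either scale.

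The other lists had 0 genes called over all genes. Adjusted over the list alone, flowering time had 1 above and 2 below, heat shock 1 below, and auxin, elongation and cell cycle 1 below. Camera called none of these lists, with adjusted p from 0.10 (jasmonate and wounding) to 0.98 (ethylene, among others). The medians of the abscisic acid, auxin, clock, DNA methylation, ethylene, jasmonate and oxidative stress lists were negative, as were the means, while camera pointed up.

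With limma 8 of 17207 genes were called, 0 above and 8 below the mid-parent, and 2207 had an unadjusted p under 0.05. With the log2 mid-parent, in the fit of the 12 libraries, 90 were called, 71 above and 19 below, 3 of them shared with the 8. The count was 1 without ZT0, without ZT15, or without the library ColxC24 ZT0, C24xCol ZT0, ColxC24 ZT6 or ColxC24 ZT15, 2 without C24xCol ZT15, and 15 without C24xCol ZT6. The F test for a dependence on time called 0 genes with limma, and 2 without ZT6. An unadjusted p under 0.05 was found for 505 of 17207 genes, a share under the 0.05 that no dependence would give. In simulated data this test recovered 10% of genes with a change of 2.

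At single times the hybrids were described without a test. Genes of a list can vary together, which the random lists do not carry, so a median outside them is a description only. The median of the defence list against the mid-parent was -1.07 at ZT0 and -0.66 at ZT15, both below the random lists, and 0.24 at ZT6, above them. WRKY70, a transcription factor gene of the salicylic acid pathway, was at 343 RPKM in C24, 14.9 in Col, 21.7 in ColxC24 and 69.1 in C24xCol at ZT0. The antenna list was at 0.36, 0.25 and 0.26 at ZT0, ZT6 and ZT15, above the random lists, except at ZT6 with quantile normalization, where 0.13 was inside their central 95%. The cold-response list was at -0.14, -1.43 and 0.22, outside the random lists at ZT6 and ZT15. Its mid-parent at ZT6 includes the Col library that stood apart in this list, so the -1.43 moves with that library. The evening-phased clock was above the random lists at ZT6 (0.16) and below them at ZT15 (-0.31). Jasmonate and wounding was above them at ZT6 (0.26), as were glucosinolates (0.10, 0.28 and 0.17) and starch metabolism (0.10, 0.10 and 0.11) at ZT0, ZT6 and ZT15, and abscisic acid at ZT15 (0.14). Below them at ZT0 were senescence (-1.39, with only 4 genes tested), oxidative stress (-0.25) and abscisic acid (-0.26), the last not with median-of-ratios scaling or quantile normalization. The other list medians were inside the central 95% of random lists.

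The median of all genes was -0.13 at ZT0 and -0.09 at ZT6 for hybrids, -0.19 at ZT6 and -0.16 at ZT15 for parents, and 0.20 at ZT6 between reciprocal hybrids. With median-of-ratios scaling these were -0.03, -0.00052, 0.02, -0.01 and 0.0075.

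Both hybrids were above both parents in 9 genes at ZT0, 23 at ZT6 and 30 at ZT15, and below both in 57, 123 and 28. These counts include organelle loci, above both parents at ZT15 and below both at ZT0 and ZT15. Among them, ATCG00020 was at 254 RPKM in ColxC24 and 136 in C24xCol at ZT15, against 80.6 in Col and 67.1 in C24. Chloroplast loci held 1.25% of all RPKM in ColxC24 and 0.87% in C24xCol at ZT15, against 0.58% in Col and 0.73% in C24. The balance depended on the scaling: at ZT0 20 were above and 30 below with median-of-ratios scaling, and 23 and 23 with quantile normalization. At ZT6 56 were above and 107 below with the former and 60 and 120 with the latter, so more genes were below than above with each scaling. At ZT0 XTH33, a cell wall enzyme gene, was at 22.0 RPKM in ColxC24, against 7.53 in Col and 7.67 in C24, and SWEET17, of the sugar transporter family, was at 37.3 RPKM in ColxC24 and 41.5 in C24xCol against 19.3 and 19.9. At ZT6 TCH4, a touch-induced cell wall gene, was at 4.27 RPKM in ColxC24 and 5.30 in C24xCol against 58.3 in Col and 42.6 in C24. WRKY54, a transcription factor gene of the defence list, was at 15.6 and 31.1 RPKM in the hybrids at ZT6 against 2.94 and 4.74, while PR5 of the same list was below both parents, at 23.1 and 16.8 against 74.6 and 121. Of this list 3 genes were above both parents at ZT6 and 1 below. At ZT15 SUC1, a sucrose transporter gene, was at 37.3 and 38.3 RPKM in the hybrids against 84.7 and 75.5.

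Hybrids against parents gave 66 genes at ZT0, 146 at ZT6 and 58 at ZT15. Col and ColxC24 against the other two gave 285, 389 and 83, and Col and C24xCol against the other two gave 81, 651 and 41. The hybrids were set apart from the parents in fewer genes than these pairings, except for the second at ZT15, an exception that ended with pseudocount 0.1 (112 against 132). With a 2-fold gap the second pairing also gave fewer genes at ZT0 (7 against 14). Both of these pairings set Col apart from C24, so genes that differ between the parents can enter their counts. They are therefore no chance level for the count of hybrids against parents.

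**Figure D2:**
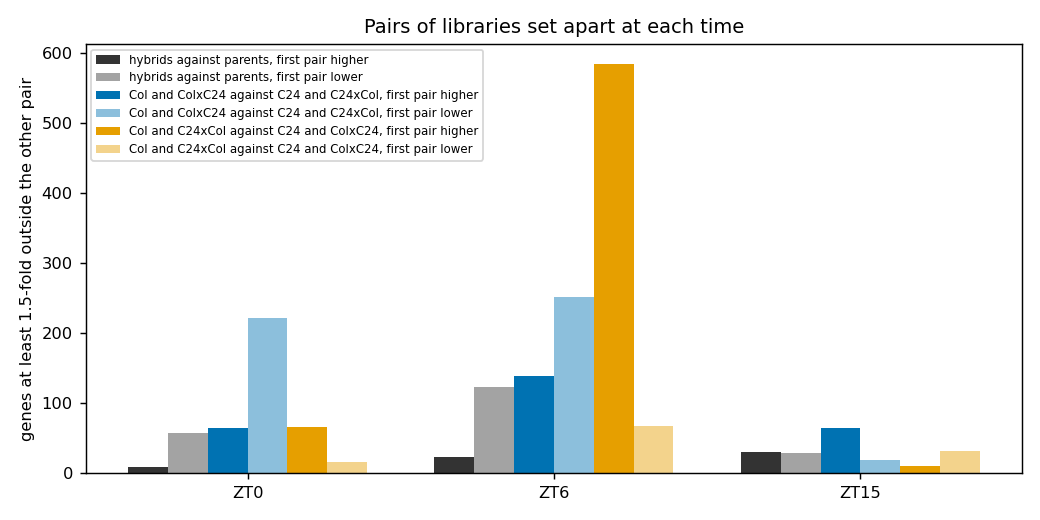
Number of genes at least 1.5-fold outside the other pair at each time (vertical axis, genes) for each pairing of the 4 libraries; bars start at 0 and have no error because there are no replicates. Hybrids against parents gave 66, 146 and 58 genes, and Col and C24xCol against C24 and ColxC24 gave 651 at ZT6.

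**Figure D3:**
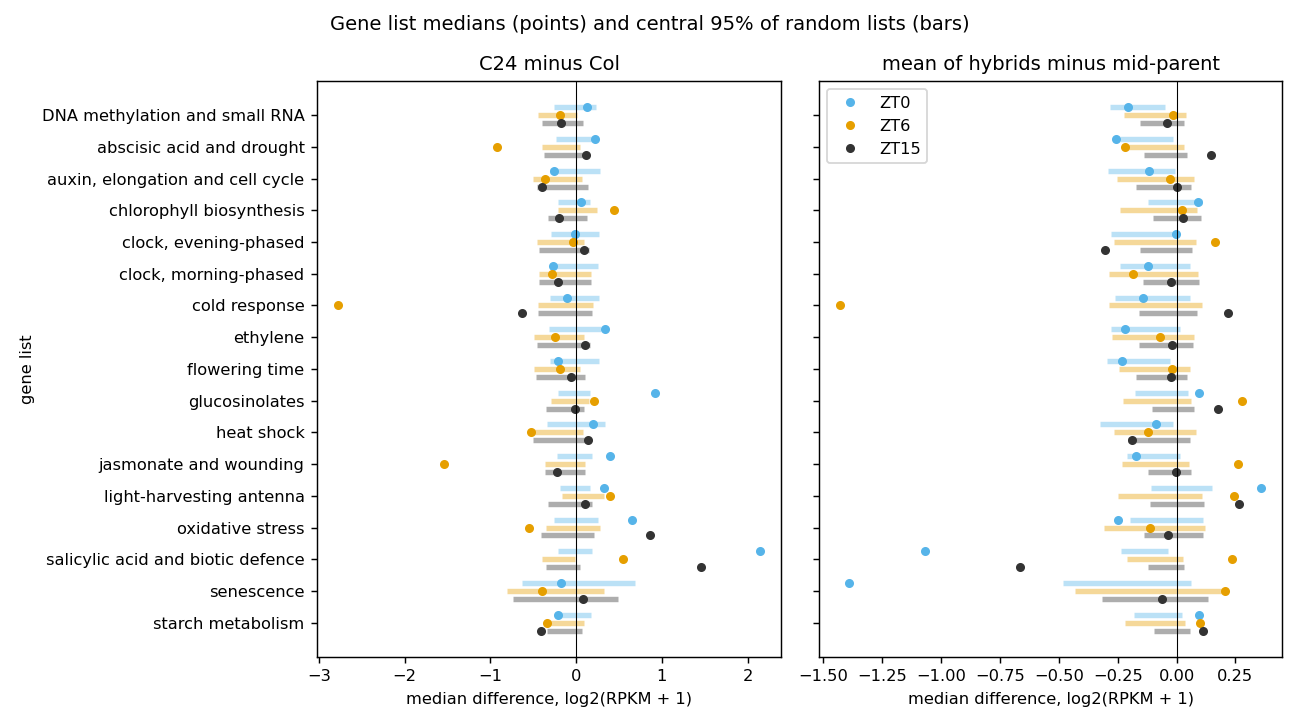
Median log2 difference (horizontal axis) of 17 gene lists at each time, with bars for the central 95% of 10000 random lists. The defence list was at -1.07 in hybrids against the mid-parent at ZT0, and the cold-response list at -2.77 for C24 minus Col at ZT6.

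The reciprocal hybrids were compared to ask whether the direction of the cross mattered. WRKY54 was at 2.63 RPKM in ColxC24 and 13.2 in C24xCol at ZT0, and RD29A, a cold and drought gene, at 2.94 and 21.5 RPKM at ZT6; neither was called, and both were chosen after their values were seen. Camera called chlorophyll biosynthesis (adjusted p = 4.4e-07) and the antenna (adjusted p = 0.011) lower in C24xCol, and the abscisic acid, morning-phased clock and defence lists higher (adjusted p = 0.019 for each). With an estimated correlation none was called (adjusted p = 0.83 with an estimated correlation for chlorophyll biosynthesis, antenna and morning-phased clock, and 0.87 for the others). The other lists had adjusted p from 0.15 to 0.89, and heat shock had 1 gene higher adjusted over the list alone. The medians of the auxin, DNA methylation, glucosinolate and starch lists were positive while camera pointed down, with a negative mean for glucosinolates alone.

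With limma 0 genes were called between reciprocal hybrids, and 1 without ZT0 or without the C24xCol library of ZT0. An unadjusted p under 0.05 was found for 771 of 17207 genes, a share under the 0.05 that no difference would give. At ZT6 1387 genes differed over 2-fold, 1220 of them higher in C24xCol, against 204 at ZT0 and 92 at ZT15. With median-of-ratios scaling 903 of 1248 were higher in C24xCol at ZT6, and with quantile normalization 834 of 1226.

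For genes near 0 in one parent, the total level in the hybrids was set beside that of the other parent, and the alleles were not told apart. A silent gene was also not told apart from one that is absent or whose reads did not map. For 37 genes expressed in Col and near 0 in C24, the median hybrid level relative to Col was 0.452 ± 0.0451 (mean and SD over 6 hybrid libraries). For 14 genes expressed in C24 and near 0 in Col it was 0.501 ± 0.0448 relative to C24. With median-of-ratios scaling, where 33 genes met the first rule and 14 the second, these were 0.503 and 0.505. AT1G24822 and AT1G25097 of the Col set had the same mean of 17.7 RPKM and the same ratio of 0.515, and were counted separately.

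The last comparisons asked which genes followed the time of day. CCA1 and LHY, morning genes of the clock, fell by 6.96 (SE 0.17) and 7.84 (SE 0.20) on the log2 scale from ZT0 to ZT15, in 4 of 4 genotypes. TOC1, an evening clock gene, rose by 2.23 (SE 0.25) from ZT0 to ZT15, and GI by 4.08 (SE 0.23) from ZT0 to ZT6. PIF4, a growth regulator, rose by 5.47 (SE 0.15) from ZT0 to ZT6 and fell by 3.86 (SE 0.15) from ZT6 to ZT15. The antenna gene LHCB2.1 fell by 5.25 (SE 0.11) from ZT6 to ZT15.

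From ZT0 to ZT6, 17 of 20 antenna genes rose and 2 fell, also when adjusted over the list alone. Jasmonate and wounding genes rose in 19 of 22 cases and fell in 1, also adjusted over the list alone, with VSP2, a storage protein gene (log2 change 7.59, SE 0.95), and MYC2, a regulator of jasmonate responses (3.56, SE 0.39). Glucosinolate genes rose in 18 of 24 cases and fell in 1 (19 and 1 adjusted over the list alone). Cold response had 5 of 12 higher and 0 lower (6 and 0 adjusted over the list alone), with COR15A higher by 5.05 (SE 0.75), or by 4.03 without the Col library of ZT6, which stood apart in this list. The defence list had 0 higher and 6 lower (0 and 6 adjusted over the list alone), with PAD4 at -1.95 (SE 0.16). Starch metabolism had 14 higher and 6 lower, chlorophyll biosynthesis 8 and 0, the morning-phased clock 3 and 7, the evening-phased clock 6 and 5, and abscisic acid and drought 5 and 7. Auxin and elongation had 4 and 1, heat shock 3 and 1, oxidative stress 2 and 3, DNA methylation 3 and 5, ethylene 0 and 5, and senescence 0 and 2, each with the same counts adjusted over the list alone. Flowering time had 3 higher and 8 lower (3 and 9 adjusted over the list alone).

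From ZT0 to ZT15, 13 of 14 evening-phased clock genes rose and 0 fell (13 and 0 adjusted over the list alone), among them FKF1 (log2 change 3.66, SE 0.17) and ELF4 (3.67, SE 0.20). Of 12 morning-phased genes 1 rose and 8 fell (2 and 8 adjusted over the list alone). Starch metabolism had 20 of 27 higher and 4 lower, with AMY3, an amylase gene, higher by 4.04 (SE 0.18) and GBSS1, a starch synthase gene, at -4.51 (SE 0.24). Antenna genes had 2 higher and 12 lower, glucosinolates 16 and 0, chlorophyll biosynthesis 7 and 7, heat shock 5 and 1, flowering time 3 and 7, and DNA methylation 4 and 2. Cold response had 3 and 1, oxidative stress 2 and 3, abscisic acid and drought 0 and 8, and senescence 0 and 3. All of these, from starch metabolism on, had the same counts adjusted over the list alone. Jasmonate and wounding had 10 and 2 (11 and 2 adjusted over the list alone), auxin and elongation 5 and 4 (5 and 5), ethylene 1 and 4 (1 and 5), and the defence list 3 and 1 (0 and 1).

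From ZT6 to ZT15, 17 of 20 antenna genes fell and 1 rose (the same adjusted over the list alone), with LHCB2.3 at -5.92 (SE 0.18). The defence list had 9 of 27 higher and 0 lower (16 and 1 adjusted over the list alone), with PR1 higher by 2.71 (SE 0.44) and WRKY70 by 2.94 (SE 0.60). The evening-phased clock had 11 higher and 1 lower (11 and 2 adjusted over the list alone), the morning-phased clock 1 and 9 (1 and 11), starch metabolism 14 and 3 (17 and 4), and jasmonate and wounding 0 and 9 (0 and 11). Chlorophyll biosynthesis had 3 and 9 (4 and 9 adjusted over the list alone), abscisic acid and drought 1 and 6 (1 and 8), auxin and elongation 2 and 6 (2 and 7), flowering time 2 and 2 (5 and 3), and senescence 0 and 2 (0 and 3). DNA methylation had 9 and 1, glucosinolates 1 and 6, heat shock 4 and 2, ethylene 2 and 1, oxidative stress 1 and 2, and cold response 0 and 1, each with the same counts adjusted over the list alone.

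In total 6768 genes were called from ZT0 to ZT6 (2156 higher, 4612 lower), 7332 from ZT0 to ZT15 (3490 higher, 3842 lower) and 4389 from ZT6 to ZT15 (2930 higher, 1459 lower). With median-of-ratios scaling the first was 3251 higher and 3426 lower and the last 1859 and 2156, and with quantile normalization they were 3223 and 3404, and 2167 and 1949. Without ColxC24 the first count was 4433 and the last 2036, and without C24xCol the second was 4859 and the last 2825. The last was 2875 without the library ColxC24 ZT15 and 2860 without C24xCol ZT15.

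**Figure D4:**
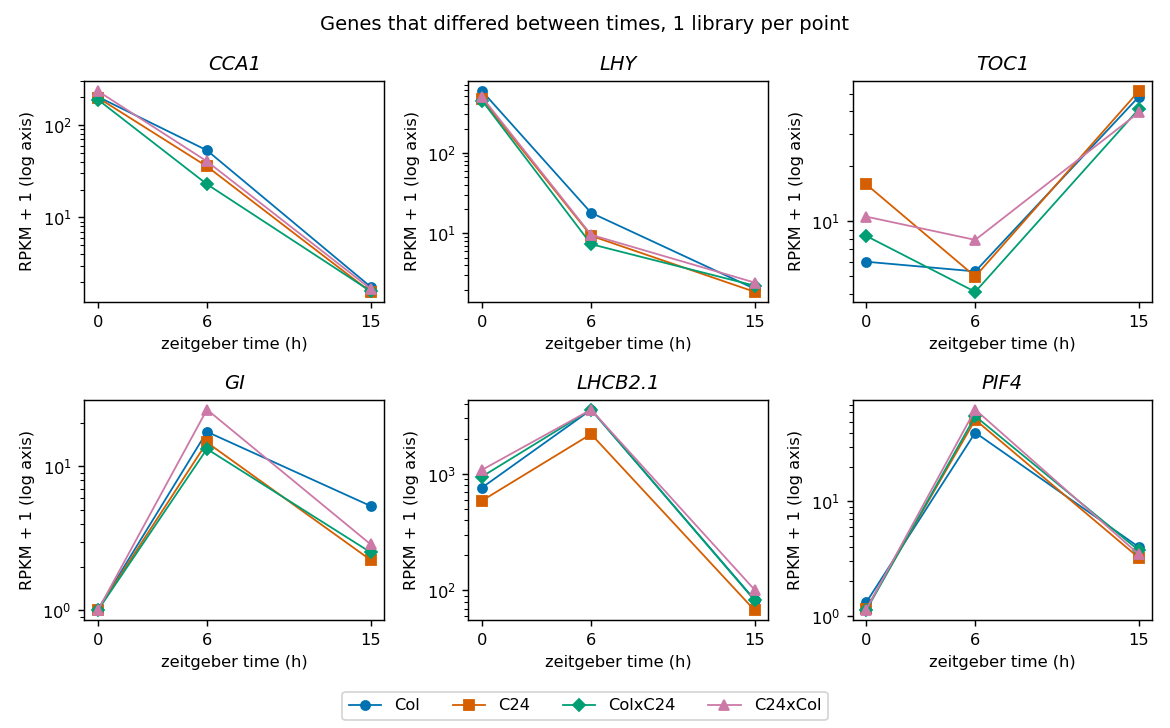
RPKM + 1 on a log axis against zeitgeber time in hours; each point is 1 library, coloured by genotype, and there are no error bars because no group has replicates. CCA1 and LHY fell by 6.96 and 7.84 on the log2 scale from ZT0 to ZT15.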

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

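The tests of scaling, of activation in C24, of the position of the hybrids, of Col RNA and of handling, and the splits of the libraries, were chosen after the results were seen; the bounds for the clock genes, the direction of the cross and the mislabelled library were written before. The cold-response list lay on opposite sides of the mid-parent at ZT6 and ZT15 in both hybrids. Its median was -2.23 in ColxC24 and -0.65 in C24xCol at ZT6, and 0.15 and 0.35 at ZT15. The difference between the times was not tested. The linear mid-parent of ZT6 includes the Col library that stood apart in this list (median of -2.77 for C24 minus Col), so the ZT6 medians move with that 1 library. Groups held 1 library each, so no search for outlying samples within groups was made.

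Cold-response genes were high in Col at ZT6, with a list median of -2.77 for C24 minus Col. A library of C24 or of a hybrid labelled as Col is argued against. For 18 genes expressed in C24 and near 0 in Col at ZT0 and ZT15, the median ratio of Col to C24 at ZT6 was 0. Any Col library would give this ratio, so it does not address a swap within Col. Another harvest time stays open, since 69.2% of 26 clock genes lay towards ZT0, between the bounds set for and against it, although 61.5 and 57.7% with median-of-ratios scaling and quantile normalization were below both. Stress or handling of the Col plants sampled and a midday response of Col cannot be told apart, because there is 1 Col library of ZT6.

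C24xCol stood apart from ColxC24 at ZT6 in 1387 genes, 1220 of them higher in C24xCol, or 903 of 1248 with median-of-ratios scaling. Another harvest time is argued against, as 46.2% of 26 clock genes lay towards ZT0 and 50% towards ZT15. An effect of the direction of the cross that holds at all times is argued against, as 80.5% of these genes differed in the same direction at ZT0 but 48.8% at ZT15 (79.5 and 46.3% with median-of-ratios scaling). Col RNA in the library cannot be told apart: genes near 0 in Col stood at 0.555 of C24 in it, against a median of 0.490 in the other 5 hybrid libraries, but at 0.507 against 0.520 with median-of-ratios scaling. An effect of the cross at ZT6 and the condition of these plants stay open, as untested.

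The median of the list of salicylic acid and biotic defence lay below the mid-parent in the hybrids at ZT0 and ZT15, without a test at single times. Scaling as the whole cause is argued against, since with quantile normalization the list median was -0.89 at ZT0 and -0.64 at ZT15, both below the random lists. On a log2 scale from Col at 0 to C24 at 1, the median position of the hybrids was 0.231 at ZT0 and 0.230 at ZT15, consistent with hybrids near the Col level at these times; it was 0.865 at ZT6. Activation in the C24 plants sampled for a reason other than genotype cannot be told apart, since C24 was above the random lists at 3 of 3 times with 1 library at each.

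For hybrids against the mid-parent 11 of 100 splits of the libraries, the real one among them, called at least 8 genes. The highest other split called 1054. The 6 splits that kept Col on the same side and C24 on the other at all times called 252 to 1054 genes. The rest called at most 137, including splits in which Col and C24 were apart at each time but changed sides between times. This points to the difference between the parents as a structure of the libraries. The splits are therefore no chance level for the 8 genes, and chance cannot be excluded. For the dependence on time the real count was 0, so all 100 of 100 splits called at least as many whatever the data (highest other 38) and decide nothing. The splits were too few for a share under 0.05 in the other comparisons. Between the parents 1 of 4 splits called as many as the real 2337 (highest other 0), and between reciprocal hybrids 4 of 4 called at least 0 (highest other 0). For the times 1 of 8 splits called as many as the real 6768, 7332 and 4389, with highest others of 0, 0 and 1.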

How the results depend on the processing

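The highest gene model, the removal of organelle and ribosomal RNA loci and the removal of single hybrid libraries from the mid-parent comparison were tried after seeing the data; the other settings were planned. The cause of the shifts was not tested, except that a stricter filter and left-out libraries leave fewer genes or columns. Of 308 named results in 7550 comparisons with alternatives, 7067 kept their side of the threshold, 476 lost the call, 5 gained it and 2 reversed. A change of sign counted as reversed only where at least 1 of the results compared was called. Sign changes of results called in neither case were not counted. Both reversals were of PR1 from ZT0 to ZT15, -0.21 and not called. With limma it was called at 0.47 without Col (adjusted p = 0.0461) and at 0.44 without the library Col ZT15 (adjusted p = 0.0458). Over all left-out groups and libraries it lay between -0.52 and 0.47. Of the called named genes, 23 of 46 between parents and 6 of 7 against the mid-parent lost the call when something was left out, and 7 of 46 and 7 of 7 under a setting. For the times, the call was lost when something was left out in 11 of 81 from ZT0 to ZT6, 8 of 82 from ZT0 to ZT15 and 16 of 77 from ZT6 to ZT15, and under a setting in 6, 3 and 10.

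With a mean of at least 5 RPKM 1289 genes were called between parents. Against the mid-parent 5 were called with pseudocount 0.1, 4 with pseudocount 0.5, 3 without a filter, 4 with a mean of at least 5 RPKM, 4 with median-of-ratios scaling, 4 with quantile normalization, 90 with the log2 mid-parent, 3 with ColxC24 alone and 2 with C24xCol alone. Leaving out times, genotypes or libraries gave 507 to 2767 genes between parents, 1 to 15 against the mid-parent, 0 to 1 between reciprocal hybrids, 4433 to 6646 from ZT0 to ZT6, 4859 to 7731 from ZT0 to ZT15, 2036 to 4718 from ZT6 to ZT15 and 0 to 2 for the dependence on time. Without organelle and ribosomal RNA loci, 2644 genes were called between parents and 8 against the mid-parent.

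With an estimated correlation the adjusted p between parents was 0.432 for the defence and antenna lists and 0.814 for glucosinolates. Against the mid-parent it was 0.0698 for the antenna, 0.196 for glucosinolates, 0.445 for starch, 0.50 for chlorophyll and 0.959 for defence. Between reciprocal hybrids it was 0.829 for chlorophyll, antenna and morning-phased clock and 0.873 for abscisic acid and defence.

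With a 2-fold gap, 3 genes were above and 11 below both parents at ZT0, 9 and 16 at ZT6, and 9 and 3 at ZT15. With pseudocount 0.1 these were 26 and 150, 40 and 189, and 47 and 65. With median-of-ratios scaling 20 were above and 30 below at ZT0 and 56 above at ZT6; with quantile normalization 23 and 23 at ZT0 and 60 above at ZT6. The level of Col-only genes in hybrids was 0.503 with median-of-ratios scaling, over 33 genes in place of 37.

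Lacking replicates, list medians with median-of-ratios scaling and pseudocount 0.1 were compared with 1 SD of the medians of random lists. Of 102 such medians, 35 shifted by at least that much. Quantile normalization was not part of this count. Medians that were inside the central 95% of random lists also changed sign, 5 with median-of-ratios scaling, 1 with pseudocount 0.1 and 10 with quantile normalization. With median-of-ratios scaling those were at ZT6, where the medians as reported were negative: DNA methylation -0.0145, auxin -0.0296, ethylene -0.0715, oxidative stress -0.112 and flowering time -0.0193, the last becoming 0.0282. With median-of-ratios scaling, at ZT0 and ZT6, they were -0.10 and 0.075 for DNA methylation, -0.14 and -0.074 for abscisic acid, -0.037 and 0.066 for auxin, 0.21 and 0.11 for chlorophyll, -0.033 and -1.25 for cold response, -0.10 and 0.047 for ethylene, and 0.22 and 0.38 for glucosinolates. They were -0.066 and 0.41 for jasmonate, -0.12 and 0.015 for oxidative stress, -0.96 and 0.31 for defence, and 0.21 and 0.22 for starch. At ZT0 flowering time was at -0.12 and the antenna at 0.49, and at ZT6 the evening-phased clock at 0.25. With pseudocount 0.1, abscisic acid was at 0.28 at ZT15, the morning-phased clock at -0.20 at ZT0, cold response at -1.61 at ZT6 and 0.30 at ZT15, heat shock at -0.25 at ZT6 and -0.35 at ZT15, defence at -1.23 at ZT0 and -0.72 at ZT15, and senescence at -1.79 at ZT0 and -0.32 at ZT15.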

Other observations

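The gene groups of this paragraph were chosen after their values were seen. In the Col library of ZT15 the anthocyanin genes LDOX, DFR and UF3GT were at 56.3, 44.6 and 31.5 RPKM, while LDOX was at 0.323 RPKM in C24, 0.374 in ColxC24 and 0.131 in C24xCol. Their regulator PAP1 was at 27.1 RPKM in Col at ZT6 and 21.6 at ZT15. For 297 genes with a ribosomal protein as product, the median of hybrids against the mid-parent was -0.27 at ZT0, -0.45 at ZT6 and -0.20 at ZT15, and -0.15, -0.34 and -0.18 with median-of-ratios scaling.

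Of 20 genes of the list for other organs and cell types, 1 was tested. Ribosomal RNA loci held 1.76% of all RPKM in C24xCol at ZT0 and 0.101% in C24xCol at ZT6, and chloroplast loci from 0.183% (C24xCol at ZT6) to 1.25% (ColxC24 at ZT15).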
